A study of Mus musculus and Bombyx mori with 12 samples.

How the data were processed

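Small RNA was sequenced from mouse testis and from BmN4 cells, an ovary-derived cell line of the silkworm Bombyx mori. The series concerns TDRD12, a Tudor domain protein, and PIWI-interacting RNAs (piRNAs), germline small RNAs that guide PIWI proteins to transposon transcripts. Per the labels, 4 libraries came from MILI immunoprecipitates (IPs) of newborn (P0) testes, 2 from Tdrd12 heterozygotes and 2 from Tdrd12 homozygous mutants. A further 2 held total small RNA of P0 testes, 1 per genotype. From testes at embryonic day 18 (E18) there was 1 MILI IP, 1 MIWI2 IP and 2 TDRD12 IPs. MILI and MIWI2 are 2 of the mouse PIWI proteins. The BmN4 libraries were 1 IP of a transfected, HA-tagged BmTdrd12 and 1 IP of the endogenous protein. In all, 12 libraries fell into 9 groups, of which 3 held 2 libraries and 6 held 1. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

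The deposited values were raw read counts, 1 for each distinct sequence, with the sequence's position, strand and a single annotation name. Per the submitters' processing notes, CASAVA 1.7 and the mouse build mm9 were used. The silkworm build, the aligner settings and the treatment of reads with several genomic matches are not given in the sources used here. Each sequence was listed at a single position, so reads of young repeats may stand at any of several near-identical copies. The authors' annotation does not give the strand of the annotated element, and genes and repeats overlapping in antisense cannot be told apart by name. The deposited counts of the mouse IPs started at 9 nt, and those of the total RNA and BmN4 libraries at 15 nt. The longest sequence had 52 nt. No molecular identifiers were stated, so intervals and floors cover counting error only.

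From these counts, reads of 24 to 33 nt were taken as the piRNA-length window. The 19713 annotation names of the mouse files were sorted by name patterns into repeat, structural RNA and miRNA lists, with 18105 names read as genes. The repeat lists were young L1, older L1, IAP, other ERVK, ERV1, ERVL and MaLR, and SINE. The structural lists were rRNA, tRNA and other structural RNA. Reads without an annotation made up 38.0% to 40.6% of the window in the P0 MILI IPs, 40.5% in the E18 MILI IP, 24.6% in the MIWI2 IP, 37.8% and 36.3% in the TDRD12 IPs, 19.3% and 19.9% in the total RNA, and 71.3% and 62.7% in the HA and endogenous BmN4 IPs. They entered the base composition and overlap values but not the feature tests or their library sizes.

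For each library the shares of reads with uridine at position 1 (1U) and, among reads without it, with adenosine at position 10 (10A) were computed with Wilson 95% intervals. 10A marks secondary piRNAs in the ping-pong cycle, whose partner piRNAs on opposite strands overlap by 10 nt at their 5′ ends. For overlaps, mouse libraries were thinned to 1887500 window reads and BmN4 libraries to 6923553. The share of reads with a partner at 10 nt was set against the mean and SD over the other overlaps from 1 to 20 nt. Partners listed on different copies of a repeat are missed by this count. Group differences of such values were tested with two-sided exact permutation tests, whose smallest possible p for 2 against 2 libraries is 0.333.

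Read counts per annotation name were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjustment at 0.05. The genotype comparison used the 4 P0 MILI IPs. The TDRD12 IPs were compared with the MILI IP and the MIWI2 IP in a fit of all 8 mouse IPs, in which the spread comes from the replicated groups and each lone library is assumed to vary like them. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, from limma 3.58.1. DESeq2 1.42.0 was an alternative. Single libraries were compared only as values, and a list's median fold was placed among 10000 random lists of equal size drawn from the 50 nearest features by abundance on each side. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 was used for the other values.

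On simulated counts for the genotype comparison (15736 features) the test recovered 9% of 2-fold and 96% of 4-fold changes, with 10 false calls among 115. For TDRD12 against MILI (16592 features) it recovered 9% and 71%, with 14 false calls among 94. For TDRD12 against MIWI2 it recovered 1% and 39%, with 2 false calls among 42. The simulated libraries shared a common composition, and changes were placed only in features with enough expected reads. These rates therefore do not cover a shift in composition such as that of the MIWI2 IP.

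The design, the lists, the alternatives and the naming rule were fixed before the data were examined. The repeat features planned by strand were replaced by features by name, since the strand of the annotated element is not given. The rule named every young L1 and IAP member, the 8 largest rises and 8 largest falls among features past the threshold with a mean of at least 100 reads and the same direction in every library, and the 5 features with most reads. For single libraries it named the 5 most abundant features and the 5 largest folds each way among features with at least 100 reads in 1 library. Features outside this rule are named as chosen after their values were seen. A feature that the rule names in the total RNA is not reported here.

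Added after the data were seen were a test of the strand ratio of internal repeat regions, a test of unannotated 10 kb windows, a check of L1Md reads for sequence shared with rRNA-annotated reads, and fits without heterozygous replicate 1. For the strand ratio, reads of each family with at least 30000 reads were linked by shared 16-mers on either strand, which left 23 of 45 families with at least 70% of reads linked. The coding strand was named for 6 families in which the assembled reads held an open frame of at least 100 codons that was at least 1.3 times the longest on the other strand. This naming was not checked against consensus sequences of the families, and some frames were short, with 108 against 76 codons in L1Md_F2 and 121 against 78 in IAPEY3-int. Reads of both strands of the 4 P0 MILI IPs were then tested with edgeR for a genotype-by-strand interaction. In simulations over 23 families the test recovered 80% of 2-fold ratio changes with 0.455% false calls.

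Alternatives covered scaling, the count filter, the libraries in the fit, the length window (25 to 28 nt, all lengths, and 26 to 30 nt for BmN4), counting each distinct sequence once, the denominator of the total RNA, and leaving out each library of a replicated group. No genome sequence was used.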

Results

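Small RNAs in IPs of MILI, MIWI2 and TDRD12 were sequenced from mouse testes. Total small RNA of newborn testes and small RNA in BmTdrd12 IPs of silkworm BmN4 cells were sequenced too. The 12 libraries held between 9071424 and 19246231 reads. In the window of 24 to 33 nt, the P0 MILI IPs held 10191638 and 10481792 reads from heterozygotes and 9946105 and 7565654 from mutants. The total RNA libraries held 3433241 and 2994719 window reads from the heterozygote and the mutant. At E18 the MILI IP held 10933395, the MIWI2 IP 7869757, and the TDRD12 IPs 3793608 and 1887500. The HA and endogenous BmN4 IPs held 6923553 and 8937459.

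Reads annotated to Tdrd12 itself were too few to check the genotype labels. There were 1 and 1 in the heterozygous MILI IPs, 3 and 2 in the mutant MILI IPs, and 1 in each total RNA library. The E18 MILI IP had 3, and the MIWI2 and TDRD12 IPs had none. Piwil2, the gene of MILI, had 224 and 271 reads in the heterozygous IPs and 209 and 217 in the mutant IPs.

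Reads in the MILI IPs peaked at 25 nt in both genotypes and at both labelled ages, and so did those in the TDRD12 IPs. The MIWI2 IP peaked at 27 nt, with 32.6% of its window reads at that length. The total RNA of the heterozygote peaked at 27 nt with 16.3%, and that of the mutant at 24 nt with 19%. The heterozygote had 13.3% at 24 nt. Of these window reads, 9.65% in the heterozygote and 15.9% in the mutant were annotated to miRNA. Structural RNA took another 27.5% and 28.5%, so the peaks are not those of piRNAs alone.

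**Figure D1:**
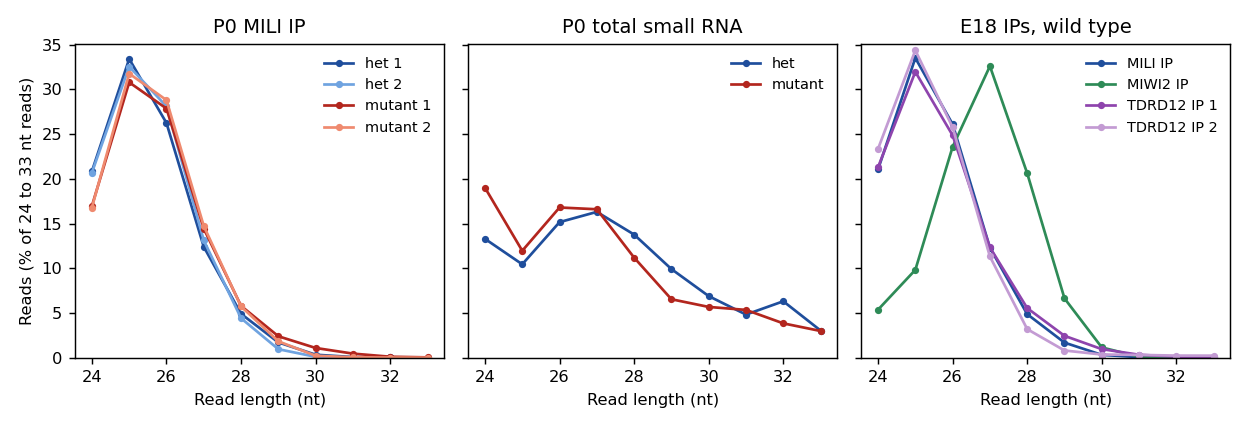
Length of reads in the 24 to 33 nt window (x axis, nt) as a percentage of window reads (y axis), with 1 line per library for the P0 MILI IPs, the P0 total small RNA and the E18 IPs. MILI and TDRD12 IPs peak at 25 nt and the MIWI2 IP at 27 nt.

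Heterozygous replicate 1 of the P0 MILI IPs and the E18 MILI IP were closer to each other than any other pair of mouse IPs. Over features with at least 50 summed reads, the squared difference of their counts had a median 1.19 times that of sampling noise, and a mean of 1.24. The median was 2.30 for the TDRD12 IPs, which are the shallowest, 2.89 for the mutant pair and 7.98 for the heterozygous pair, and the means for the first 2 of these were 10.7 and 7.88. A ratio this near to sampling noise cannot tell separate libraries from the same RNA under 2 labels. Both were kept as separate libraries only because their labels give different ages and genotypes. If the RNA is the same, they are not independent. The edgeR counts with TMM from fits of all 8 mouse IPs in the window are therefore also given without heterozygous replicate 1. Such fits also take the heterozygous pair, the widest of the replicated pairs, out of the spread. A rise in calls may therefore come from the smaller spread alone.

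The loss of TDRD12 was examined first through the base composition of MILI-bound piRNAs, since the series concerns secondary piRNA biogenesis. In the P0 MILI IPs, the 10A share of non-1U reads was 37.5% ± 0.40 (SD, n = 2) in heterozygotes and 31.9% ± 0.56 (n = 2) in mutants. The difference of −5.62 points was −3.02 at all lengths and −3.51 over distinct sequences. Young L1, the list of 6 L1Md retrotransposon families, had the widest gap among the repeat lists, with 51.5% and 45.9% in heterozygotes against 32.6% and 32.2% in mutants. IAP, an endogenous retrovirus group, had 54.4% and 56.8% against 45.5% and 46.3%. ERV1 had 54.7% and 53.2% against 46.6% and 46.3%, and SINE 37.2% and 39.5% against 31.4% and 32.0%. Reads annotated to genes differed least of these, with 27.7% and 28.7% against 25.5% and 25.6%.

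Older L1 elements had 10A shares of 41.1% and 40.9% in heterozygotes and 32.8% and 33.5% in mutants. ERVL and MaLR elements had 42.8% and 42.9% against 36.7% and 36.8%, and other ERVK elements 46.2% and 45.1% against 40.8% and 41.2%. Unannotated reads had 34% and 36.2% against 29.9% and 30.3%. Both mutants thus lay below both heterozygotes in 9 of 9 groups, gene reads included, each with p = 0.333 in the two-sided exact permutation test, the smallest value it can give. Some reads listed at young L1 shared a 20-mer with rRNA-annotated reads. Without them the young L1 shares were 55.5% and 51.5% in heterozygotes and 38.1% and 37.4% in mutants. Among 1U reads the 10A share was 24.2% in heterozygotes and 24.3% in mutants, with overlapping libraries.

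**Figure D2:**
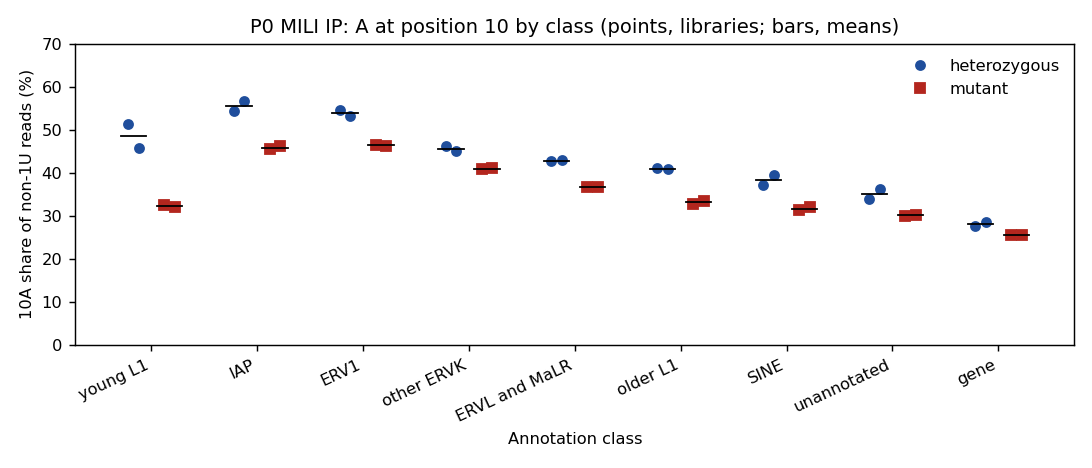
Share of non-1U reads with A at position 10 (y axis, percent) by annotation class (x axis) in the P0 MILI IPs, with 1 point per library and bars at the mean of 2 libraries. Both mutants lie below both heterozygotes in every class drawn, with young L1 at 32.6% and 32.2% against 51.5% and 45.9%.

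The 1U share was 84.5% ± 1.95 (SD, n = 2) in heterozygotes and 87.7% ± 0.56 in mutants. IAP made up 2.54% ± 0.155 of window reads in heterozygotes and 3.53% ± 0.257 in mutants, and ERV1 2.62% and 2.79% against 3.08% and 3.72%. SINE made up 9.64% and 10.8% against 8.27% and 7.73%, and genes 21.5% and 21.8% against 23.7% and 22.8%. Young L1 overlapped between genotypes, with 1.64% and 0.962% against 1.31% and 1.67%. Where the genotypes did not overlap, the exact permutation p was again 0.333.

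Opposite-strand partners at 10 nt were less frequent in the mutant MILI IPs. At equal depth, 1.52% and 1.98% of heterozygous reads and 0.844% and 0.953% of mutant reads had such a partner. Partners at the other overlaps were less frequent in both mutants too, at 9 nt with 0.576% and 0.711% against 0.368% and 0.451%. Position pairs at 10 nt numbered 6556 and 6696 in heterozygotes and 4233 and 4550 in mutants. At 9 nt they numbered 3147 and 3240 against 2228 and 2527. Relative to 9 nt, the fall was thus much smaller than the fall in the excess below. That excess is a difference from the background and is not scaled to it. Above the mean of the other overlaps, the excess was 1.06 percentage points ± 0.23 (SD, n = 2) in heterozygotes and 0.431 ± 0.032 in mutants (exact permutation p = 0.333). The difference of −0.632 points was −0.301 over distinct sequences and −1.29 without thinning to equal depth. Among unannotated reads the excess was 1.14 and 1.52 against 0.450 and 0.510, and among gene reads 0.631 and 0.885 against 0.28 and 0.233. Young L1 reads had 0.0953 and 0.309 in heterozygotes and −0.0309 and −0.0409 in mutants. SINE reads had 0.529 and 0.717 against 0.285 and 0.393. IAP reads had 0.111 and 0.136 against 0.441 and 0.156, a gap that rests on mutant replicate 1. The ratio of IAP position pairs at 10 nt to those at other overlaps was 1.87 and 2.53 against 1.66 and 1.59. Such a ratio is given here for no other class. ERV1 and older L1 overlapped. The 10 nt overlap still stood above the other overlaps in both mutants, by 3.51 and 3.93 SDs, against 7.82 and 12.9 SDs in heterozygotes.

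**Figure D3:**
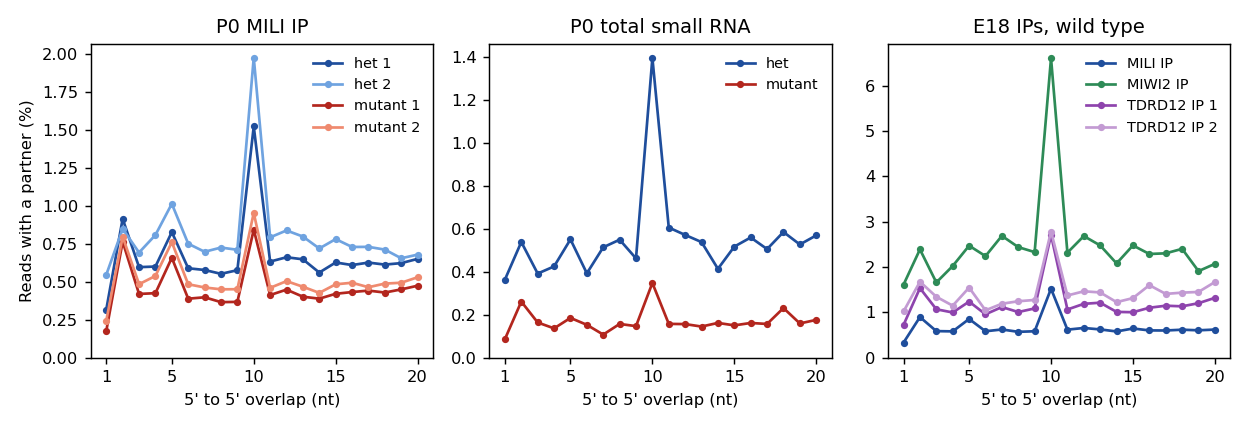
Share of reads with a partner on the opposite strand (y axis, percent, on a different scale in each panel) by the overlap of their 5′ ends (x axis, nt) at equal depth, with 1 line per library. At 10 nt the heterozygous MILI IPs reach 1.52% and 1.98%, the mutants 0.844% and 0.953%.

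Strand use was examined for 23 internal repeat regions, a test added after the data were seen. The L1Md_A family had 48.7% and 56.1% of reads on its coding strand in heterozygotes and 75.2% and 72.6% in mutants, so that its coding to noncoding ratio rose by 1.37 on the log2 scale (SE 0.19, adjusted p = 0.0238). MMERGLN-int, an endogenous retrovirus, went from 48.4% and 50.1% to 62.4% and 62.9% (log2 change 0.79, adjusted p = 0.0238). The ratio of MERVL-int, an endogenous retrovirus known for its expression in early embryos, rose by 0.76 (adjusted p = 0.0424), from 78.0% and 82.2% to 86.8% and 87.7%. IAPEY3-int went the other way, from 66.9% and 73.6% to 52.7% and 52.5%, and its ratio fell by 1.10 (adjusted p = 0.0279). Its strand was named from a frame of 121 against 78 codons, and a wrongly named strand would turn this direction. IAPEz-int was split within heterozygotes, with 55.6% and 78.0% against 86.2% and 84.1% in mutants, and did not pass (adjusted p = 0.181). L1Md_F2, with 46.4% and 53.9% against 54.7% and 57.8%, did not pass either (adjusted p = 0.230).

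On the noncoding strand of L1Md_A, 60.2% and 46.3% of all reads had A at position 10 in heterozygotes and 28.6% and 30% in mutants. On its coding strand the shares were 32% and 33.3% against 23.7% and 23.9%. The noncoding strand of IAPEz-int had 60.8% and 54.2% against 37.9% and 36.3%, that of L1Md_F2 47.6% and 34.3% against 21.3% and 21.8%, and that of MMERGLN-int 37.3% and 36.5% against 32.2% and 33%. MERVL-int barely separated on that strand, with 50.2% and 39.3% against 37.8% and 38.6%, and IAPEY3-int went the other way, with 28.9% and 26.5% against 29.6% and 30.4%. Of the 23 regions, 10 passed the edgeR test, of which 8 had a higher and 2 a lower ratio in mutants. The coding strand could be named in 6 regions, from open frames alone and without a check against known sequences, and for the rest the direction is arbitrary. Without heterozygous replicate 1 the test called 11 regions, without heterozygous replicate 2 it called 16, and without either mutant library 0. In each of these fits the spread comes from the other genotype's pair alone, and the lone library is assumed to vary like that pair.

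**Figure D4:**
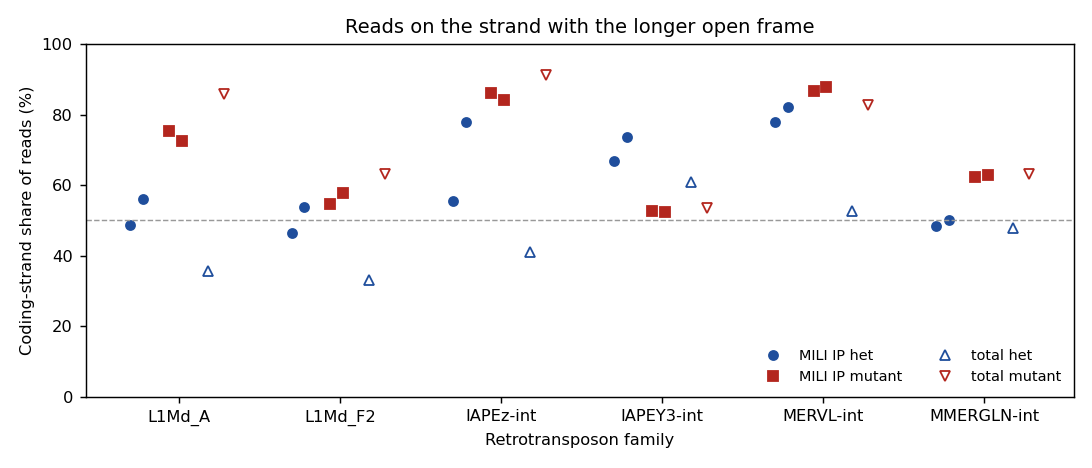
Share of reads on the coding strand (y axis, percent) for the 6 retrotransposon families whose coding strand could be named (x axis), with 1 point per library of P0 MILI IPs (filled) and total small RNA (open). L1Md_A moves from 48.7% and 56.1% in heterozygous MILI IPs to 75.2% and 72.6% in mutants.

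The abundance of MILI-bound piRNAs was then compared feature by feature. Of the 16 IAP features, 3 rose in mutants over all features tested. IAPEz-int, the internal region of the common IAP family, rose 1.82-fold, from a mean of 7610 to 13844 CPM (n = 2 and 2; log2 change 0.86, SE 0.10, adjusted p = 0.0468). IAPLTR1_Mm rose 3.05-fold (adjusted p = 0.0290) and IAPLTR4_I 3.36-fold (adjusted p = 0.0434). Of the IAP list, 13 had a positive log2 change with TMM scaling, with DESeq2's size factors and with library size only. IAPLTR2_Mm (1.40), IAPLTR1a_Mm (1.28), IAPEY2_LTR (−1.16), IAPEy-int (−0.31) and IAP-d-int (−0.20) did not pass over all features. Adjusted over the list alone, 10 were higher and 2 lower. The 3 calls ended without either mutant library, while IAPLTR2_Mm, IAPLTR1a_Mm, IAPLTR2a, IAPLTR4 and IAPEY2_LTR passed over all features without either heterozygous library.

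SINE members had a negative log2 change in 31 of 31 cases under each of these scalings, with a median of −0.35 with TMM. None passed in the edgeR test over all features, 19 had an unadjusted p under 0.05, and 17 were lower adjusted over the list alone. DESeq2 called 2 of them. B3, the most abundant SINE, had a log2 change of −0.37 (adjusted p = 0.153, or 0.0450 without heterozygous replicate 1). None of the 6 young L1 features passed with any of these scalings or adjusted over the list alone, the smallest unadjusted edgeR p being 0.314 for L1Md_Gf. Their log2 changes ran from −0.30 for L1Md_Gf to 0.32 for L1Md_A, and these depend on single libraries. L1Md_A stood at 1.27 (adjusted p = 0.000184) without heterozygous replicate 1 and at −0.24 (adjusted p = 0.400) without replicate 2. L1Md_F2 stood at 0.52 (adjusted p = 0.0457) and −0.23, L1Md_T at 0.49 and −0.26, and L1Md_Gf at 0.12 and −0.63. Of 83 other ERVK features, 4 were higher and 11 lower adjusted over the list alone, with a median of −0.20. ERV1 had 1 higher of 20 and rRNA 2 lower of 4 in that count. Older L1 (97 features) and ERVL and MaLR (109 features) had 0 in that edgeR count, with 6 and 17 at an unadjusted p under 0.05. DESeq2, adjusted over all features, called 1 higher and 1 lower older L1 and 0 ERVL and MaLR features.

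With camera at the preset correlation, IAP was higher (adjusted p = 1.63e-05), SINE lower (adjusted p = 5.32e-06) and other ERVK lower (adjusted p = 0.0140). None of these calls held, at adjusted p = 0.915 for each with an estimated correlation. With fry, which tests whether a list's members move one way on balance, only ERVL and MaLR passed, towards lower (adjusted p = 0.00190), and its median turned from negative to 0.01 with library size only. Young L1 (adjusted p = 0.866), rRNA (adjusted p = 0.190), tRNA and other structural RNA did not pass camera.

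Reads of single genes made up most of the other calls. BC003267 fell 15.8-fold in mutants (adjusted p = 0.0209) and Cdv3 fell 9.91-fold (adjusted p = 0.0290). Zfp524, which encodes a zinc finger protein, fell 6.59-fold, Fbxo27, an F-box gene, 5.97-fold, and Ppp2r5a, which encodes a regulatory subunit of a protein phosphatase, 5.77-fold. 4930519F16Rik and Tmprss9, a serine protease gene, fell 4.56-fold and 4.20-fold, and Fundc1 fell by 2.49 on the log2 scale. Thbd, the gene of thrombomodulin, rose 9.46-fold, Enpp1, an ectonucleotide pyrophosphatase gene, 10.6-fold, and Ghr, the growth hormone receptor gene, 7.17-fold. Gabrb1, a GABA receptor subunit gene, rose 5.38-fold, Cdh3, a cadherin gene, 4.90-fold, and Sorcs2, of the sortilin receptor family, 3.91-fold. Mier3 (log2 change 2.63), Sema3c (2.67), Akr1c14 (4.36) and Cdh19 (6.74) also rose. These last 4 and Fundc1 had means below 100 reads and were named after their values were seen. None of these calls held without either mutant library. The names say where the reads lie, not that the transcripts of these genes changed.

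In all, 21 of 15736 features passed the edgeR test, 13 higher and 8 lower in mutants, and 2248 had an unadjusted p under 0.05. DESeq2 called 269, 135 higher and 134 lower, and library size only gave 9 higher and 3 lower. With the replicate number as a block the count was 266, at all lengths 9, and with all 8 mouse IPs in the fit 234, or 2205 without heterozygous replicate 1. With the 4 P0 MILI IPs it was 2338 without heterozygous replicate 1, 718 without heterozygous replicate 2, and 0 without either mutant replicate 1 or mutant replicate 2. With 1 of these 4 left out, the spread comes from the other genotype's pair alone and the lone library is assumed to vary like that pair, so these counts depend on which pair sets the spread. Without the low-count filter the count was 0.

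Total small RNA of P0 testes shows the same genotypes before any IP, with 1 library each and therefore no replicate check and no p-value. Reads of 24 to 33 nt made up 27.7% of reads in the heterozygote and 18.6% in the mutant, while miRNA reads made up 56.0% and 68.5%. The share of young L1 in all reads was 4.63-fold lower in the mutant (counting interval 4.58 to 4.67), the widest gap among the repeat lists, and 5.66-fold lower per miRNA read. Without reads sharing a 20-mer with rRNA-annotated reads it was 6.98-fold lower (6.89 to 7.06). ERV1 was 2.74-fold lower, older L1 2.69-fold, other ERVK 2.49-fold, ERVL and MaLR 2.12-fold, IAP 2.06-fold and SINE 1.98-fold. Gene reads were 1.06-fold lower, rRNA 1.5-fold and tRNA 1.59-fold, and other structural RNA was 1.05 times the heterozygote's level.

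Among young L1, L1Md_Gf was 14.1-fold lower in the mutant total RNA, L1Md_F 6.41-fold, L1Md_T 6.32-fold, L1Md_A 6.31-fold, L1Md_F2 5.61-fold and L1Md_F3 1.95-fold. The median fold of other ERVK lay at percentile 0 of random lists of matched abundance, that of young L1 at 0.015, ERV1 at 0.07, IAP at 12.7, ERVL and MaLR at 20.5, older L1 at 25.4 and SINE at 95.2. The share of L1Md_F3 reads with a 20-mer of rRNA-annotated reads was 64.2% in the heterozygote and 89.9% in the mutant. Within IAP, IAPEY2_LTR was 4.92-fold lower, IAPLTR2b 3.56-fold, IAPLTR3 3.42-fold, IAPEz-int 1.71-fold and IAPLTR1_Mm 1.08-fold. The satellite GSAT_MM was 75.7-fold lower, BC003267 26.6-fold, Cdv3 15.4-fold and OTTMUSG00000011270 11.2-fold. GSAT_MM also varied within genotype, with 10201 and 723 reads in the heterozygous MILI IPs against 764 and 1124 in the mutant ones, so its fold may not reflect genotype. Higher in the mutant were Cd93 (8.44-fold), Dusp6 (7.01-fold), Fmod (6.97-fold) and Cd82 (6.88-fold). The most abundant features of the window were tRNA-Gly-GGY, LSU-rRNA_Hsa, tRNA-Glu-GAG_, SSU-rRNA_Hsa and 5S.

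The 10A share of non-1U reads was 25.7% in the heterozygous and 16.9% in the mutant total RNA, miRNA and structural RNA reads of the window included. Young L1 had 50.7% and 19.8%, or 61.1% and 29.7% without rRNA-like reads, IAP 64.4% and 43.8%, and ERV1 63.5% and 47.3%. The excess of 10 nt overlaps was 0.890 and 0.187 percentage points. At 9 nt, 0.462% and 0.147% of reads had a partner, so the background was lower in the mutant as well. The coding-strand share of L1Md_A was 35.8% and 85.8%, and that of IAPEz-int 41.1% and 91.2%. MERVL-int had 52.6% and 82.8%, MMERGLN-int 47.8% and 63.0%, L1Md_F2 33.2% and 63.1%, and IAPEY3-int 61.0% and 53.4%.

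The most abundant miRNA hairpins of the total RNA had, per miRNA read, mutant to heterozygote ratios of 1.03 for mir-199a-2, 0.902 for mir-10b, 0.952 for mir-99a, 0.881 for mir-148a and 1.07 for mir-26a-2. Of the let-7 family, 10 of 11 hairpins were above 1 with a median of 1.15, at percentile 99.7 of random lists. Striated muscle miRNAs lay below 1 in 4 of 4 cases, with a median of 0.505 (percentile 0), mir-1-2 at 0.549, mir-133a-1 at 0.556, mir-133b at 0.444 and mir-206 at 0.465. Blood cell miRNAs were below 1 in 5 of 5 cases, with a median of 0.721 (percentile 0.145), among them the erythroid mir-451 at 0.797. The liver miRNA mir-122 stood at 0.324 from 122 and 63 reads.

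Among miRNAs linked to germ cells, the median ratio in the total RNA was 0.962 for miR-290 to miR-295 (percentile 31.9) and 0.962 for the miR-17 to miR-92 cluster (percentile 39.7). The gonadal soma miRNA miR-202 stood at 0.882, and the smooth muscle hairpins mir-143 and mir-145 at 1.22 and 0.934. Meiotic hairpins had a median of 0.855 (percentile 4.44), with mir-34c at 0.830 and mir-449a at 1.35, and miR-302 had 25 and 22 reads, too few for a fold. The largest ratios were those of mir-184 (1.92), mir-141 (1.64), mir-463 (1.63), mir-7b (1.62) and mir-465a (1.60). Besides those of muscle and liver, mir-685 (0.466) and mir-805 (0.480) were among the lowest.

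The E18 IPs ask which PIWI protein's piRNAs the small RNAs in the TDRD12 IPs resemble. The series holds no control IP, such as a TDRD12 IP from mutants. The values below thus cannot tell RNA held with TDRD12, directly or through a partner, from piRNAs carried through the IP. TDRD12-bound here means present in a TDRD12 IP. TDRD12 IPs had 80.9% and 79.1% 1U reads, against 86.0% in the MILI IP and 69.8% in the MIWI2 IP. Their 10A share of non-1U reads was 34.4% ± 1.08 (SD, n = 2), against 37.4% with MILI and 61.2% with MIWI2. Young L1 made up 2.10% and 2.25% of TDRD12-bound reads, 1.60% of MILI-bound and 6.86% of MIWI2-bound reads. Without rRNA-like reads the order against MILI turned, with 1.44% and 1.18% for TDRD12, 1.55% for MILI and 6.78% for MIWI2. IAP made up 2.46% and 2.16%, against 2.63% and 7.78%, ERV1 2.52% and 2.70%, against 2.61% and 8.84%, and genes 21.4% and 20%, against 21.5% and 7.30%. The widest 95% Wilson interval among these shares, that of 10A, reached 0.147 percentage points to either side.

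TDRD12 IPs held more structural RNA. They also held more reads under 15 nt, 31.9% and 49.0% of all reads, against 5.62% with MILI and 10.6% with MIWI2. Only 37.2% and 20.8% of their reads lay in the window, against 66.1% and 62.5%. The shares that follow are of window reads. rRNA made up 2.39% and 5.27% of their reads, against 0.513% with MILI and 0.799% with MIWI2, and miRNA 0.555% and 0.60%, against 0.0863% and 0.0872%. The 1U share of rRNA reads was 29.8% and 27.9%, against 58.9% with MILI, 44.1% with MIWI2 and 21.7% and 23.0% in the total RNA of P0 testes. Sequences shared between libraries were counted after thinning to 1887500 reads. Of these, 1820737 and 1767217 entered for TDRD12, a gap about the size of their structural RNA and miRNA reads. The shares thus do not cover all TDRD12-bound reads. Of the reads that entered, 23.4% and 22.8% had a sequence also found with MILI, and 14.2% and 13.9% one found with MIWI2. Of those of replicate 1, 26.2% were found in replicate 2. In the reverse direction, 27.2% and 24% of MIWI2-bound reads were found in the TDRD12 IPs, and 20.7% and 19.2% of MILI-bound reads. As 25.6% of MIWI2-bound reads were also found in the MILI IP, the reverse shares do not show a likeness of TDRD12 to MIWI2. The excess of 10 nt overlaps was 1.60 and 1.42 percentage points in the TDRD12 IPs, 0.902 in the MILI IP and 4.35 in the MIWI2 IP. The background differed in the same order. At 9 nt, 1.09% and 1.28% of TDRD12-bound, 0.585% of MILI-bound and 2.33% of MIWI2-bound reads had a partner. At 10 nt the shares were 2.71% and 2.78%, 1.52% and 6.61%. The excess is not scaled to this background, so it does not rank the IPs.

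**Figure D5:**
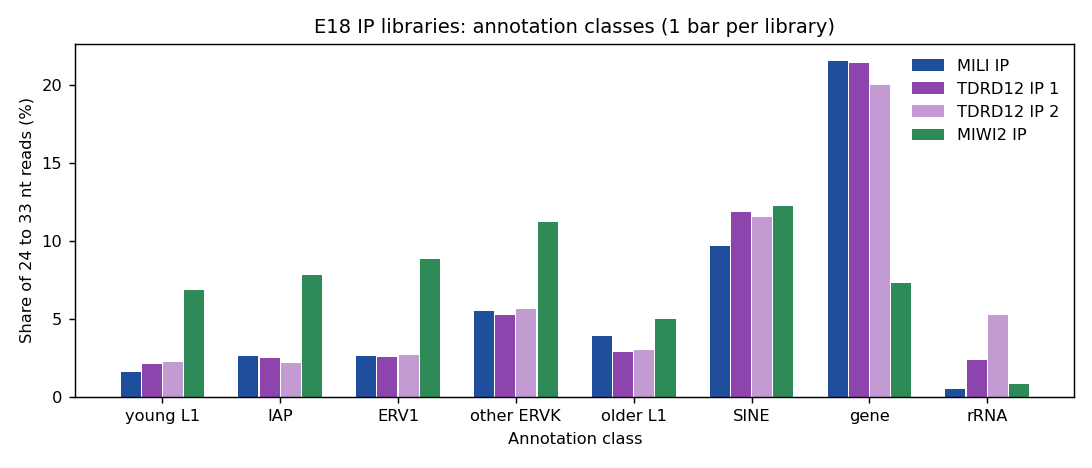
Share of 24 to 33 nt reads (y axis, percent) by annotation class (x axis) in the E18 IPs, with 1 bar per library. Young L1 makes up 2.10% and 2.25% of reads in the TDRD12 IPs, 1.60% in the MILI IP and 6.86% in the MIWI2 IP, and without rRNA-like reads 1.44% and 1.18%, 1.55% and 6.78%.

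Against the MILI IP, the TDRD12 IPs differed most in structural RNA. LSU-rRNA_Hsa, the large ribosomal RNA, was 12.6-fold higher (log2 difference 3.65, adjusted p = 0.0895; 6.81-fold without TDRD12 replicate 2) and L1Md_F3 6.00-fold higher (2.58, adjusted p = 0.0653), and neither passed with all 8 mouse IPs in the fit. Of L1Md_F3 reads, 87.5% and 92.5% in the TDRD12 IPs and 32.6% in the MILI IP shared a 20-mer with rRNA-annotated reads, and without these reads TDRD12 had 0.739 times the MILI level. B1_Mus1, a SINE, was 2.03-fold higher (adjusted p = 0.0895), and IAPEz-int had a log2 difference of 0.93 (adjusted p = 0.227). L1Md_A stood at −0.61. Heterozygous replicate 1 of the P0 MILI IPs was also left out of the fit. The log2 differences were then 3.65 for LSU-rRNA_Hsa, 2.58 for L1Md_F3, 1.02 for B1_Mus1, 0.93 for IAPEz-int and −0.61 for L1Md_A. In that fit the spread comes from the mutant and TDRD12 pairs alone, which lay closer than the heterozygous pair.

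By list, 4 of 4 rRNA, 42 of 50 tRNA, 38 of 45 other structural RNA and 113 of 136 miRNA features had a positive log2 difference against MILI. Adjusted over the list alone, 4 rRNA, 7 tRNA, 22 other structural and 54 miRNA features were higher, and 2 other structural and 1 miRNA features lower. SINE members were positive in 31 of 31 cases with TMM, 6 of them adjusted over the list alone, but in only 18 with library size only, which shifted the median of all features to −0.28. IAP had 2 higher and 3 lower adjusted over the list alone, and of older L1 only 14 of 97 were positive, or 3 with library size only.

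No feature of 16592 passed for TDRD12 against MILI in the edgeR test, a count of 0, with 2048 at an unadjusted p under 0.05. DESeq2 called 74, 68 higher and 6 lower. The counts of 1124 and 1762 below leave the heterozygous pair, the widest, out of the spread. They assume that lone libraries vary like the closer pairs, so they depend on which pairs set the spread. The count was 1124, 679 higher and 445 lower, when heterozygous replicate 1 of the P0 MILI IPs was left out of the estimate of the spread. It was 1762 when only the 4 E18 libraries gave that estimate, and 7 at 25 to 28 nt.

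Against the MIWI2 IP, the TDRD12 IPs held fewer reads of IAP and ERV1 retrotransposons under either scaling, with folds that depend on it. The same held for young L1 other than L1Md_F3, whose excess with library size only ended without its rRNA-like reads. With TMM, IAPEz-int was 18.9-fold lower (log2 difference −4.24, SE 0.19, adjusted p = 1.89e-07), and with library size only 3.45-fold lower. With TMM, IAPLTR1a_Mm was 37.2-fold, IAPLTR1_Mm 35.9-fold and MMETn-int 35-fold lower, and with library size only 6.83-fold, 6.62-fold and 6.45-fold. RLTR4_Mm was 32.5-fold lower with TMM and 5.99-fold lower with library size only, and MusHAL1, RLTR10-int and L1_Mm had log2 differences of −4.92, −4.86 and −4.80, or −2.47, −2.42 and −2.35 with library size only. Among young L1 with TMM, L1Md_Gf was 27.5-fold lower, L1Md_T 25.6-fold, L1Md_A 24.8-fold, L1Md_F2 21.5-fold and L1Md_F 17.5-fold, or between 5.04-fold (L1Md_Gf) and 3.24-fold (L1Md_F) with library size only. L1Md_F3 was 2.57-fold lower with TMM but higher with library size only, at a log2 difference of 1.06. The abundant MMERGLN-int and B1_Mus1 were 19.4-fold and 8.02-fold lower with TMM, and 3.58-fold and 1.48-fold lower with library size only.

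Against MIWI2, every measured member was lower in the edgeR test with TMM for young L1 (6), IAP (16), other ERVK (83), ERV1 (20) and SINE (31), as were 81 of 97 older L1 and 72 of 109 ERVL and MaLR features. The TMM factor of the MIWI2 IP was 0.202, against 1.13 and 1.05 for the TDRD12 IPs. With library size only, the median of all features moved from 0.13 to 2.55. IAP was then lower in 16 of 16, ERV1 in 19 of 20 and young L1 in 5 of 6, whereas SINE turned to 22 higher and 3 lower, other ERVK to 22 higher and 33 lower, older L1 to 37 higher and 13 lower, and ERVL and MaLR to 59 higher and 19 lower.

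The largest rises against MIWI2 with TMM were those of hairpin mmu-mir-222 (25-fold), mmu-mir-30a (log2 difference 3.99), mmu-mir-30d (3.67) and mmu-mir-351 (3.63). The ribosomal protein gene Rplp1 (11.1-fold), the superoxide dismutase gene Sod1 (7.39-fold), Fsd1 (2.83 on the log2 scale) and the cytochrome oxidase gene Cox6a1 (2.63) followed. With library size only the log2 differences were larger, at 7.06 for mmu-mir-222 and 5.90 for Rplp1. At 25 to 28 nt, mmu-mir-30a stood at −0.08. No longer past the threshold were mmu-mir-222, mmu-mir-30d and mmu-mir-351 at 25 to 28 nt or without either TDRD12 replicate, mmu-mir-30a and Cox6a1 without replicate 2, and L1Md_F3 without replicate 1. In all, 1091 of 16592 features passed with edgeR, 210 higher and 881 lower. With library size only, 13302 were higher and 146 lower, and the 4 E18 libraries alone gave 2314 calls. Without TDRD12 replicate 1 the count was 553, without replicate 2 it was 606, and without heterozygous replicate 1 of the P0 MILI IPs in the fit it was 1773, which include all 1091.

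The BmN4 IPs hold small RNAs recovered with the silkworm protein, with 1 library each, no control IP and no replicate check. The HA-tagged IP had 78.1% 1U reads (95% interval 78.1 to 78.2) and the endogenous IP 47.6% (47.5 to 47.6). Among non-1U reads 39.1% and 27.8% had 10A. The gap was widest in gene reads, with 76.8% and 23.8% 1U. LTR transposon reads had 84.9% and 71.2% 1U and 56.0% and 40.7% 10A, and LINE reads 76.8% and 59.8% 1U and 50.6% and 36.3% 10A. The excess of 10 nt overlaps was 24.8 percentage points in the HA IP and 13.4 in the endogenous IP. Reads peaked at 28 nt and 27 nt.

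Silkworm genes took 8.96% of the HA-bound and 16.4% of the endogenous-bound window reads, LTR transposons 8.86% and 10.5%, and LINE elements 7.74% and 7.59%. The gypsy-Ty3-like element, with most reads, had an HA to endogenous ratio of 1.07, SART 1.25, L1Bm-2 0.891 and Pao-like-2 0.715, and the PAO element was 2.27-fold higher in the endogenous IP. Higher with HA were the genes BGIBMGA006321 (11.6-fold) and BGIBMGA009774 (7.40-fold), the tRNA Asp(GTC) (6.72-fold), bmo-mir-965 (5.22-fold) and BGIBMGA008628 (5.17-fold). Higher in the endogenous IP was BGIBMGA000140, at 13 against 5849 reads (349-fold). The spliceosomal RNA U12, with 2 HA and 1013 endogenous reads, had an HA to endogenous ratio of 0.00255 (counting interval 0.000637 to 0.0102). BGIBMGA000783, BGIBMGA008122 and BGIBMGA010263 had 1 HA read each and 427, 263 and 260 endogenous reads, with ratios of 0.00302 (0.000425 to 0.0215), 0.00491 (0.000689 to 0.035) and 0.00496 (0.000697 to 0.0354).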

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

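The tests below were all chosen only after the results they bear on were seen.

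Several classes went one way between genotypes in both replicates of the MILI IP and the other way in the total small RNA, where each genotype has 1 library. IAP took 0.994 percentage points more of the window reads in the mutant MILI IPs, and its difference was −0.894 points in the total RNA. ERV1 had 0.693 points in the MILI IP and −1.21 in the total RNA. Other repeats and names had 0.286 and −0.723, and unannotated reads −1.62 and 0.590. The difference between the IP and the total RNA was not tested.

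Reads under 15 nt, which lie outside the 24 to 33 nt window, made up 5.62% of reads in the E18 MILI IP and 49.0% in TDRD12 replicate 2. TDRD12 replicate 1 had 31.9%, the MIWI2 IP 10.6%, and the P0 MILI IPs from 6.61% to 17.6%.

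The mutant MILI IPs had a lower 10A share and fewer 10 nt overlaps. Partners at the other overlaps were fewer too. Unequal depth was argued against by the difference in overlap excess of −0.632 points at equal depth, against a combined SD of 0.232. Heterozygous replicate 1 as the sole origin was argued against by heterozygous replicate 2, from which the mutants differed by −5.91 points of 10A (SD of mutants 0.564). More structural RNA in mutants was argued against by the lower 10A share in both mutants in 7 of the 7 repeat lists. This included young L1 without its rRNA-like reads (38.1% and 37.4% against 55.5% and 51.5%). With TMM, the median log2 change in the mutant MILI IPs was −0.57 for rRNA, −0.08 for tRNA and 0.18 for other structural RNA. A rise across these lists was thus not seen, and setting it aside adds little to the 10A result. A loss of secondary piRNAs with the loss of TDRD12 is a hypothesis that stays open, as do litter and strain background, which the mixed background of the mice leaves untested.

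Heterozygous replicate 1 of the P0 MILI IPs lay close to the E18 MILI IP. The same RNA under 2 labels is a candidate explanation, since the pair's median ratio to sampling noise was 1.19 and the next lowest, that of the shallower TDRD12 IPs, 2.30. Whether MILI IPs are alike at both ages stays open, since heterozygous replicate 2 stood at 8.10 from the E18 MILI IP but also at 7.98 from heterozygous replicate 1. From the E18 TDRD12 IPs, the E18 MILI IP stood at 6.14 and 5.69, and heterozygous replicate 2, labelled P0, at 3.98 and 2.98. From the mutants, the E18 MILI IP stood at 6.33 and 7.23, heterozygous replicate 1 at 6.24 and 7.12, and heterozygous replicate 2 at 10.1 and 8.52. These values leave the E18 MILI IP in doubt as the age-matched comparator of the TDRD12 IPs. They do not decide which label would be wrong, and no other biological explanation was tested.

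L1Md_F3 and rRNA reads were more abundant in the TDRD12 IPs than in the MILI IP, although neither L1Md_F3 nor LSU-rRNA_Hsa passed the edgeR test with all 8 mouse IPs in the fit. For L1Md_F3, rRNA fragments listed at its positions are a candidate explanation. A mean of 90.0% of its reads in the TDRD12 IPs shared a 20-mer with rRNA-annotated reads, and the rest stood at 0.739 times the MILI level. For rRNA, unbound RNA carried through the IP may account for the excess, since 28.8% of its reads were 1U in the TDRD12 IPs against 58.9% in the MILI IP. Binding of rRNA fragments by TDRD12 itself stays open and was not tested.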

How the results depend on the processing

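Several alternatives were chosen only after the results were seen. They were fits without heterozygous replicate 1 where it only sets the spread, and the genotype fit of the other 7 mouse IPs. Overlaps without thinning, young L1 without rRNA-like reads and fry as an alternative to camera were others. Leaving out libraries in the strand and window tests was also chosen then. Restriction to uniquely mapped reads was not run, since the files do not mark them. The causes of the changes below were not tested unless stated.

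For genotype, 21 features passed. DESeq2 called 269, library size only 12, no count filter 0, the fit with all 8 mouse IPs 234 (2205 without heterozygous replicate 1) and all lengths 9. Replicate numbers are shared by the genotypes, but with 2 pairs they are not stated to pair the samples (correlation of deviations 0.139). With the replicate number as a block, 266 passed. Leaving out 1 library gave 0 to 2338, where the lone library is assumed to vary like the other genotype's pair. For TDRD12 against MILI, where 0 passed with edgeR, DESeq2 called 74, 25 to 28 nt gave 7, the 4 E18 libraries alone 1762, and leaving heterozygous replicate 1 out of the fit 1124. Leaving out either TDRD12 library gave 0. For TDRD12 against MIWI2, with 1091, library size only gave 13448, the 4 E18 libraries alone 2314, the fit without heterozygous replicate 1 gave 1773, and leaving out 1 TDRD12 library 553 to 606. L1Md_F3 reversed to 1.06 with library size only, and mmu-mir-30a to −0.0808 at 25 to 28 nt. Without its rRNA-like reads, L1Md_F3 was not higher, at 923 and 821 CPM of window reads with TDRD12 against 4487 with MIWI2. Features that passed neither in the comparison nor in the alternative changed sign too. Against MILI, library size only gave −0.0574 for IAPLTR4_I, −0.227 for L1Md_F2 and −0.0201 for L1Md_Gf, and 25 to 28 nt gave −0.0140 for L1Md_F2. Without 1 TDRD12 library, IAPLTR1a_Mm ran from −0.350 to 0.0195, L1Md_F2 from −0.0331 to 0.104 and L1Md_Gf from −0.0487 to 0.473. For genotype, L1Md_F turned to 0.0240 with library size only, and L1Md_F3 to −0.124 and L1Md_T to −0.0599 at 25 to 28 nt. With all 8 mouse IPs but heterozygous replicate 1, L1Md_F stood at 0.191 and L1Md_Gf at 0.114. Without 1 P0 MILI IP, IAPLTR3 ran from −0.136 to 0.327, L1Md_A from −0.244 to 1.27, L1Md_F from −0.254 to 0.195, L1Md_F2 from −0.230 to 0.521, L1Md_F3 from −0.290 to 0.278, L1Md_Gf from −0.628 to 0.118 and L1Md_T from −0.256 to 0.494, of which L1Md_A and L1Md_F2 passed at their highest values. Of the 3 lists called by camera, 0 were called with an estimated correlation, and fry called 1 list. Leaving out 1 library gave 0 to 16 regions in the strand test and 0 to 598 windows in the window test, under the same assumption.

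The genotype difference in 10A was −5.62 points, −3.02 at all lengths, −3.51 over distinct sequences, and −6.02 to −5.22 without 1 library. The 10A share of the TDRD12 IPs was 34.4%, 36.5% at 25 to 28 nt, 24.1% at all lengths, and 33.6% to 35.2% without 1 library. The genotype difference in overlap excess was −0.632 points, −0.301 over distinct sequences, −1.29 without thinning, and −0.795 to −0.469 without 1 library. The mutant to heterozygote ratio of young L1 in total RNA was 0.216, 0.177 per miRNA read, 0.236 at 25 to 28 nt, 0.285 over distinct sequences, and 0.143 without rRNA-like reads. Ratios of other classes crossed 1 over distinct sequences for rRNA (1.08), tRNA (1.07) and genes (1.3), and per miRNA read for other structural RNA (0.861). The 1U gap between the BmN4 IPs was 30.6 points, 28.3 at 26 to 30 nt and 28.5 over distinct sequences.

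The next counts leave out the main value of each comparison and all values of the overlaps, lists, strand ratios and windows. Over the other named features and values, 1195 alternative values were computed. Of 980 from feature tests, 813 kept direction and side of the threshold, 81 lost it, 61 gained it and 25 changed direction. Of 215 without a test, 131 stayed within the spread, 80 moved beyond it and 4 reversed. For single libraries a counting interval stood in for the spread. Values with a library of a pair left out could not move beyond the spread. The shift in the pair's mean is then always smaller than the pair's SD. A reversal was counted only where the compared values stood apart, and 210 of the 215 kept their direction. Of the 215, 75 were values of the E18 composition, which are percentages and cannot change direction. The counts of 131 and 210 thus include values whose label was fixed in advance, and they do not measure robustness. TDRD12 replicate 2 held 1887500 window reads, the fewest of the 12 libraries, which limits the precision of its values. The test of TDRD12 against MIWI2 recovered only 39% of 4-fold changes simulated without a shift in composition between libraries.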

Other observations

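The window test and its minimum were chosen only after the data were seen. A first run on all windows recovered none of the simulated changes, so windows of 10 kb with a mean of at least 500 unannotated reads were kept, 1016 in number, which hold 30.8% of the unannotated reads. In simulations on these windows the test recovered 6% of 2-fold and 72% of 4-fold changes, with 1 false call among 79.

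Unannotated piRNA loci differed between genotypes in both directions in the P0 MILI IPs. On mm9, chromosome 14 from 121200001 to 121210000 had 2521 and 2375 reads in heterozygotes and 169 and 130 in mutants (log2 change −3.65, edgeR adjusted p = 0.0322). Chromosome 12 from 55810001 to 55820000 had 5275 and 4960 against 580 and 476 (log2 change −2.89, adjusted p = 0.0322). Chromosome 2 from 35860001 to 35870000 rose, from 403 and 320 to 1897 and 1399 (log2 change 2.56, adjusted p = 0.0495). Its plus-strand share was 40.9% and 44.1% in heterozygotes and 15.2% and 17.9% in mutants. Chromosome 14 from 66240001 to 66250000 rose by 1.88 on the log2 scale, and its plus-strand share was 21.6% and 22.1% against 4.79% and 4.34%. In all, 14 windows passed, 6 higher and 8 lower, and 322 had an unadjusted p under 0.05. Without heterozygous replicate 1 the count was 598, without heterozygous replicate 2 it was 360, and without either mutant library 0, the lone library being assumed to vary like the other genotype's pair. The annotation of genes around these windows was not used here.

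In the chromosome 7 windows given here, chosen after their values were seen, at most 0.0479% of reads of any library lay on the plus strand. From 6590001 to 6600000 there were 12493 and 9536 reads in heterozygotes and 4723 and 3786 in mutants (adjusted p = 0.0888). From 6600001 to 6610000 there were 9702 and 4179 against 11931 and 8278 (adjusted p = 0.244). The log2 changes of these windows were −0.99 and 0.90. Nearby windows from 6560001 to 6570000 and from 6580001 to 6590000 had log2 changes of 0.23 and 0.61. None passed, and differences between the windows were not tested.

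Reads of the GSAT_MM satellite varied widely between IPs of the same kind. There were 10201 in heterozygous replicate 1 and 10775 in the E18 MILI IP, against 723 in heterozygous replicate 2, 764 and 1124 in mutants, 1144 in the MIWI2 IP and 88 and 69 in the TDRD12 IPs. In the total RNA there were 6343 in the heterozygote and 109 in the mutant. The median ratio of heterozygous replicate 2 to sampling noise was 3.98 and 2.98 against the TDRD12 IPs and 7.98 against heterozygous replicate 1. The mean ratios were 24.7 and 34.4 against 27.0.

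In the endogenous BmN4 IP, the 100 most frequent sequences without 1U took 16% of window reads, against 5.80% in the HA IP. Of reads without 1U, 23.8% were annotated to genes in the endogenous IP and 9.53% in the HA IP. At equal depth, 88.7% of HA reads had a sequence found in the endogenous IP and 75.9% of endogenous reads one found in the HA IP. Of distinct sequences, 36.7% and 23.1% were shared.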
